A study of Homo sapiens with 6 samples.

How the data were processed

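RNA was sequenced from human embryonic stem cells of 2 lines, Royan H6 (RH6) and Royan H5 (RH5). Cells of each line were held either in the naive state of pluripotency, which resembles the cells of the embryo before implantation, or in the primed state in which such lines are usually grown. Per the labels' protocols, naive cells had been induced with a condition named 2a2iL and were then kept in 2iL medium, primed cells were kept in medium with bFGF, and both grew on inactivated mouse embryonic fibroblasts. State and medium therefore changed together, and no library separates them. There were 4 naive libraries, 2 of each line, and 2 primed libraries, 1 of each line. The passage number was 10 for naive RH6, 17 for naive RH5, 20 for primed RH6 and 16 for primed RH5. Nothing in the labels says that the duplicate naive libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

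Per the labels' protocols, RNA above the size of small RNA was purified with on-column DNase digestion, libraries were made with a stranded total RNA kit, and at least 30 M paired-end reads of 75 bases were sequenced on a NextSeq500. The molecule field of the labels says polyA RNA, which differs from the total RNA kit. The submitters' processing notes name FastQC, STAR 2.4.0a, featureCounts 1.4.5-p1 of the Subread package and DESeq2, and the builds hg19 and GRCh37.p5, with no role or order. The gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart. The reference annotation at hand is of another build, so no coordinates are given.

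The authors deposited whole-number read counts per gene, not normalized, in 1 table of 63677 genes with Ensembl identifiers and symbols. The 498 genes of XIST, TSIX and the Y chromosome were left out before any step, which left 63179. All 37 genes of the mitochondrial genome were at 0 in every library, so the list of mitochondrial genome genes could not be tested. Total counts per library were 13435699 to 14637860 after this step, and the largest library held 8.9% more than the smallest. Duplicates were compared by a chi-square of their counts per gene over genes with at least 10 counts in the pair. The chi-square per gene was 9.23 between the naive RH6 libraries and 5.76 between the naive RH5 libraries, where counting noise alone gives about 1, and 18.70 to 72.19 between libraries of different groups. The duplicates therefore differed by more than counting noise and were kept as separate libraries.

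Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test on the deposited counts with TMM normalization. The TMM factors were 0.964 to 1.029. Genes were kept by filterByExpr with the state as group, with a minimum count of 10 and a minimum total of 15, which left 19389 genes. Naive against primed was fitted on all 6 libraries with the line as a covariate, with 3 residual degrees of freedom. The biological coefficient of variation was 0.189, and in this fit the spread includes the difference of the state effect between the lines. Naive against primed within each line, the difference of the state effect between the lines and the comparison of naive RH6 with naive RH5 were contrasts of a fit with 1 mean per group, with 2 residual degrees of freedom and a coefficient of variation of 0.096. There the spread came from the naive duplicates alone, and each lone primed library was assumed to vary like them. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, two-sided, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. A rank or permutation test of a single gene over 4 against 2 libraries cannot give an exact one-sided p under 0.067. CPM values use the TMM-scaled library sizes. Principal components used log2 CPM with a prior count of 2.

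A total of 27 gene lists held 587 distinct genes, of which 584 were found, and some genes stood in more than 1 list. The lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes. Camera asks whether the genes of a list are shifted relative to all other genes. Members of each list were counted with p-values adjusted over all genes and also adjusted over the list alone. Camera with the correlation estimated from these libraries, and fry, which asks whether a list's genes move on balance in 1 direction without reference to other genes, were the alternatives. Of the lists, those for fibroblasts, neural cells, mesendoderm and endoderm, trophectoderm and germ cells stood for other cell types that the cultures could hold.

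The genes named in the text were chosen by a rule. For naive against primed it took 15 genes of pluripotency, DNA methylation, NR5A2, RARG and the TGFβ pathway whatever their result. It also took the 8 higher and 8 lower called genes of largest log2 fold change with a mean log2 CPM of 3 or more and the same side in both lines, and up to 4 members of each list with the smallest adjusted p. For the difference between the lines, and for naive RH6 against naive RH5, it took the 5 highest and 5 lowest called genes with a mean log2 CPM of 3 or more. Clone names, small RNA genes and pseudogenes were passed over. Groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined. Some genes that the rule took are not reported here. Other genes named are said to have been chosen after their values were seen.

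Where a gene had 0 counts in a group, its fold is given as a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of summed counts per library size is given with a 95% counting interval, from the exact binomial interval. Bounds and intervals cover counting error only. Medians of lists are of fitted log2 fold changes, and are given also with genes at 0 counts set to their bound where this changed the value.

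The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with 100 genes changed by 1 and 100 by 2 on the log2 scale. Their spread was that of the fit with 1 mean per group, for primed and naive libraries alike. The simulated state effect of naive against primed did not differ between the lines. The numbers therefore check the scripts and may be more favourable than in the real libraries. For naive against primed, 70 and 94 of these were recovered, and 9 other genes of the 18647 tested were called. For RH6, 51 and 84 were recovered with 10 others called, and for RH5, 51 and 78 with 7 others, among the same number of genes. For the difference between the lines, 36 and 71 were recovered with 25 others called among 18676 genes, and for naive RH6 against naive RH5, 70 and 87 with 27 others. In a simulation of 18674 genes with 1 changed list and 20 null lists, each of the 3 set tests called the changed list. Both forms of camera called 0 of the 20 null lists and fry called 1. The simulated genes were drawn independently of each other, while the estimated correlation in the real lists reached 0.665, for neural and ectoderm markers. The simulation thus cannot show how often camera at the preset correlation calls correlated lists falsely.

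The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter beyond 1 count, a filter of 1 CPM in 2 libraries, and leaving out histone and mitochondrial genes. Further alternatives were leaving out each library in turn, no line term, the naive libraries of each line summed, and the replicate number as a block in the comparison of the naive lines. Without a line's lone primed library, the fit of naive against primed holds the effect of the other line alone. Such a run repeats that line's own effect and adds no independent support. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.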

Results

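Gene expression was measured by RNA sequencing in naive and primed human embryonic stem cells of 2 lines, RH6 and RH5. The 6 libraries held 14637860 and 14097536 counts for naive RH6, 14009382 and 13477795 for naive RH5, 14505776 for primed RH6 and 13435699 for primed RH5. Between 29971 and 31445 genes had at least 1 count in a library. Across genes, log2 CPM correlated at 0.988 between the naive RH6 duplicates and 0.989 between the naive RH5 duplicates. The correlation was 0.956 to 0.958 between naive libraries of different lines, 0.974 between the primed libraries and 0.906 to 0.926 between naive and primed libraries.

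**Figure D1:**
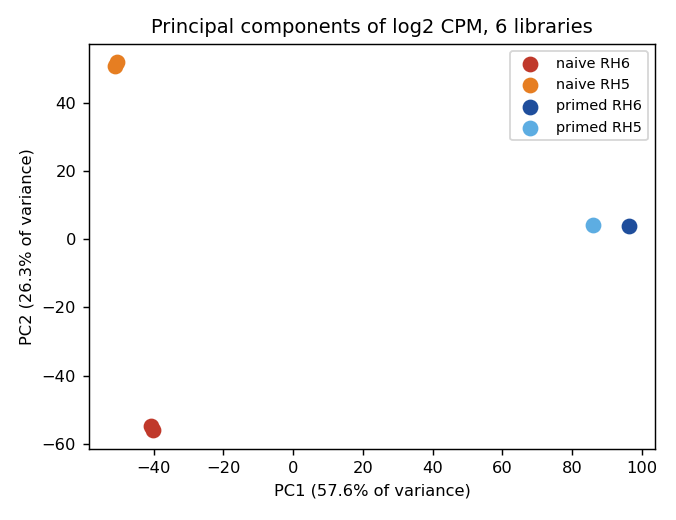
Principal components of log2 CPM, with 1 point per library, PC1 on the horizontal and PC2 on the vertical axis with the percent of variance of each. PC1, with 57.6% of the variance, placed the 4 naive libraries between -51.2 and -40.1 and the primed libraries at 86 and 96.4, and PC2, with 26.3%, placed naive RH6 at -56.1 and -54.8 and naive RH5 at 50.9 and 51.9.

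The main comparison asked how the transcriptome of naive cells differed from that of primed cells over both lines. Naive cells held far more mRNA of HPGD (ENSG00000164120), which breaks down prostaglandins, at 392.2 ± 34.6 CPM (SD, n = 4) against a mean of 3.13 CPM in primed cells. Its log2 fold change was 7.01 ± 0.40 (SE, adjusted p = 1.09e-04). The mesoderm and trophoblast transcription factor HAND1 (ENSG00000113196) rose by 6.67 ± 0.23 on the log2 scale (adjusted p = 3.98e-05). APLNR (ENSG00000134817), the apelin receptor, rose by 6.15 ± 0.34, the primitive streak factors T (ENSG00000164458) and MIXL1 (ENSG00000185155) by 5.34 ± 0.47 and 5.02 ± 0.22. The GABA receptor subunit gene GABRB2 (ENSG00000145864) rose by 4.88 ± 0.14, the proton pump gene ATP12A (ENSG00000075673) by 4.80 ± 0.26, and ERVH48-1 (ENSG00000233056), which derives from an endogenous retrovirus, by 4.72 ± 0.18. These 8 genes had adjusted p-values of 2.60e-05 to 5.29e-04 and were higher in all 4 naive libraries than in the primed library of the same line.

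Among the genes lower in naive cells, the calcium channel gene CACNA1H (ENSG00000196557) had the largest fall under the rule, with a log2 fold change of -5.09 ± 0.21 (adjusted p = 5.50e-05). MACC1 (ENSG00000183742) stood at 3.26 ± 0.36 CPM (SD, n = 4) in naive cells against a mean of 102.5 CPM in primed cells, a log2 fold change of -4.97 ± 0.13. The tryptophan-degrading enzyme gene IDO1 (ENSG00000131203) had a log2 fold change of -4.90 ± 0.16 and the receptor gene GPR176 (ENSG00000166073) of -4.99 ± 0.54. The neural transcription factor gene SOX21 (ENSG00000125285) had a fold change of -5.04 ± 0.82 (adjusted p = 0.0055), made up of -6.82 in RH6 and -2.81 in RH5. It was -2.80 without primed RH6, where only the RH5 effect remains. Its call was lost with the naive libraries of each line summed (adjusted p = 0.0665). The long noncoding RNA RMST (ENSG00000255794) had -4.01 ± 0.35, the potassium channel gene KCNG3 (ENSG00000171126) -3.94 ± 0.16 and the secreted Wnt modulator gene SFRP1 (ENSG00000104332) -3.92 ± 0.18.

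Of the 19389 genes tested, 5000 were called by edgeR's quasi-likelihood test, 2351 higher and 2649 lower in naive cells. At least 2-fold changes were held by 1259 of the higher and 1739 of the lower genes. In 4971 of the 5000, all naive libraries lay on the same side of their line's primed library in both lines. The fit counts a difference of the effect between the lines as spread, so this agreement was partly set by the test. Of all genes tested, 68% had log2 fold changes of the same sign in both lines. Fewer genes were called when a naive library was left out, with 3320 and 3021 without naive RH6 replicates 1 and 2, and 3012 and 3368 without naive RH5 replicates 1 and 2. With the naive libraries of each line summed, 1125 genes were called.

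The title of the series names NR5A2, RARγ and the TGFβ pathway in the induction of the naive state, so these genes and general markers of pluripotency were examined whatever their result. NR5A2 (ENSG00000116833), a nuclear receptor that regulates POU5F1, had a log2 fold change of 1.30 ± 0.40 in naive cells and was not called (adjusted p = 0.0538). It was called with DESeq2 (adjusted p = 0.0044), with limma-voom (0.0239) and with no low-count filter (5.84e-04). Its effect was 2.35 ± 0.16 in RH6 (adjusted p = 2.14e-06) and 0.44 ± 0.15 in RH5. Without primed RH6 the estimate was 0.45 and without primed RH5 2.38, each being the other line's effect again. The call in RH5 (adjusted p = 0.0411) was lost with DESeq2 (0.2179), limma-voom (0.0518), upper-quartile factors (0.0707), no low-count filter (0.0649) and without naive RH5 replicate 1 (0.1194) or 2 (0.0769). RARG (ENSG00000172819), which encodes RARγ, was lower in naive cells, at 18.3 ± 2.26 CPM (SD, n = 4) against a mean of 38.0 CPM, with a log2 fold change of -1.05 ± 0.13 (adjusted p = 0.0022). Its call was lost with the naive libraries summed (adjusted p = 0.0584).

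The TGFβ family ligand gene NODAL (ENSG00000156574) rose by 4.00 ± 0.41 on the log2 scale (adjusted p = 9.35e-04), with 4.99 in RH6 and 3.22 in RH5. The nodal antagonist gene LEFTY1 (ENSG00000243709) rose by 2.47 ± 0.36 (adjusted p = 0.0035) and the inhibitory SMAD gene SMAD7 (ENSG00000101665) by 1.74 ± 0.20 (adjusted p = 0.0014). LEFTY2 (ENSG00000143768), at 2.52 ± 0.91, was not called over both lines (adjusted p = 0.0858). It was called in each line alone, at 5.27 ± 0.16 in RH6 (adjusted p = 4.33e-08) and 1.00 ± 0.12 in RH5 (adjusted p = 1.13e-04). Over both lines it was called with limma-voom (adjusted p = 0.0285) and with no low-count filter (3.56e-04). Without primed RH6 the estimate was 1.01 and without primed RH5 5.30, each being the other line's effect again.

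The core pluripotency factor gene POU5F1 (ENSG00000204531) stood at 407.6 ± 70.7 CPM (SD, n = 4) in naive cells against a mean of 349.7 CPM in primed cells, and its log2 fold change of 0.22 ± 0.18 was not called (adjusted p = 0.4286). The effect of POU5F1 was 0.49 ± 0.18 in RH6 and -0.04 ± 0.18 in RH5. In RH6 it was not called (adjusted p = 0.0584), nor with limma-voom or upper-quartile factors. It was called there with DESeq2 (adjusted p = 0.0354), RLE factors (0.0499) and no low-count filter (2.15e-04). Without primed RH5, where only the RH6 effect remains, the effect of POU5F1 was 0.53. SOX2 (ENSG00000181449) fell, with a log2 fold change of -1.33 ± 0.15 (adjusted p = 0.0012). NANOG (ENSG00000111704) was not called, at 0.65 ± 0.27 (adjusted p = 0.1235), but was at 0.67 with no low-count filter (adjusted p = 0.0192). Its effect was 1.33 ± 0.14 in RH6 (adjusted p = 4.77e-05) and 0.06 ± 0.14 in RH5 (adjusted p = 0.7822). Without primed RH5, where only the RH6 effect remains, the estimate was 1.35. The naive factor genes KLF4 (ENSG00000136826), at -0.23 ± 0.17, and TFCP2L1 (ENSG00000115112), at -0.09 ± 0.21, were not called (adjusted p = 0.3579 and 0.803). KLF17 (ENSG00000171872), another naive factor gene, had 33 counts over the 4 naive libraries, 31 of them in RH5, and 0 in the primed libraries, at least 5.7-fold higher (adjusted p = 0.0341). That call was lost with DESeq2 (0.0550), limma-voom (0.0740), no line term (0.1552), without naive RH6 replicate 2 (0.0533) and without primed RH5 (0.4124). The DNA methyltransferase gene DNMT3B (ENSG00000088305) fell, with a log2 fold change of -2.20 ± 0.12 (adjusted p = 9.87e-05), and its catalytically inactive cofactor gene DNMT3L (ENSG00000142182) rose by 5.61 ± 0.27 (adjusted p = 6.50e-05). The primed factor gene ZIC2 (ENSG00000043355) fell, at -1.27 ± 0.24 (adjusted p = 0.0091), with -0.65 in RH6 and -1.82 in RH5. It was -0.62 without primed RH5, where only the RH6 effect remains. It was not called without the line term (adjusted p = 0.2748) or with the naive libraries summed (0.0906).

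**Figure D2:**
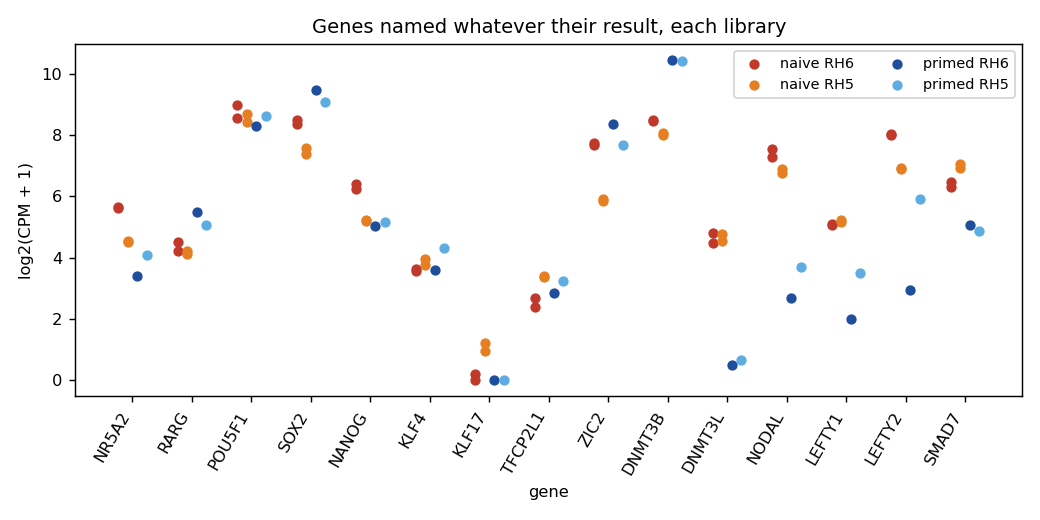
Expression of the 15 genes examined whatever their result, as log2(CPM + 1) on the vertical axis, with 1 point per library coloured by group. DNMT3B lay at 252.3 to 353.4 CPM in the 4 naive libraries and at 1365.6 and 1389.3 CPM in the primed libraries, while POU5F1 overlapped between the states.

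The gene lists for pluripotent states moved with the state of the cells, with members that went against their list. Of 23 tested genes of naive pluripotency, 11 rose and 4 fell (13 and 4 adjusted over the list alone), with a median log2 fold change of 1.38 (camera adjusted p = 8.00e-06). The adjusted p was 0.1022 with an estimated correlation. The other 7 genes of this list were not tested. DPPA5, KHDC3L, KHDC1L, ARGFX, HORMAD1 and TRIM60 had 1 to 8 counts over all 6 libraries and ESRRB had 24, of which 11 were in primed RH6. NLRP7, a maternal-effect gene, rose by 3.98 ± 0.16, and TFAP2C, a transcription factor of naive cells and trophoblast, by 1.38 ± 0.14. The 4 that fell, chosen after their values were seen, were VENTX (-1.11), PRDM14 (-0.73), DPPA4 (-0.66) and ST6GAL1 (-0.46). Of 28 tested genes of primed pluripotency, 19 fell and 5 rose (20 and 5 adjusted over the list alone), with a median of -0.8 (camera adjusted p = 3.05e-09, and adjusted p = 0.1614 with an estimated correlation). The receptor phosphatase gene PTPRZ1 had a log2 fold change of -3.77 ± 0.13, the deubiquitinase gene USP44 of -3.06 ± 0.10 and B3GAT1, which makes the HNK-1 epitope, of -2.64 ± 0.14. The 5 that rose were T (5.34), the neuropeptide gene NTS (2.55), the intermediate filament gene VIM (1.53), the histone demethylase gene KDM6B (1.20) and the cadherin gene CDH2 (0.88), of which NTS, KDM6B and CDH2 were chosen after their values were seen. Of 15 genes shared by both states, 10 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.75, -0.45 in RH6 and -1.03 in RH5 (camera adjusted p = 1.00e-05, and adjusted p = 0.1614 with an estimated correlation). They included UTF1 at -2.93 ± 0.27, the epithelial cadherin gene CDH1 at -1.14 ± 0.11 and SOX2.

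Signalling lists moved as well. Of 22 tested response genes of Wnt and beta-catenin, 16 rose and 0 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 1.43 (camera adjusted p = 4.71e-19, and adjusted p = 0.1022 with an estimated correlation). They included SP5, a direct target, at 3.79 ± 0.17, the ligand gene WNT3 at 2.62 ± 0.14, and MIXL1 and T. The homeobox gene CDX1 was 145-fold higher by summed counts, with a counting interval of 39.9 to 1200, from 558 counts in naive and 2 in primed libraries. Targets of TGFβ, activin and nodal rose in 12 of 25 and fell in 0 (12 and 0 adjusted over the list alone), with a median of 0.91, 1.47 in RH6 and 0.49 in RH5 (camera adjusted p = 1.07e-09, and adjusted p = 0.1551 with an estimated correlation). They included the feedback regulator gene PMEPA1 at 2.21 ± 0.20 and the smooth muscle gene TAGLN at 1.75 ± 0.15. Of the 25 targets, 12 were also in another list. Components of the same pathway went both ways, with 8 of 32 higher and 7 lower (8 and 7 adjusted over the list alone), a median of -0.2 and a mean of 0.04 (camera adjusted p = 0.9985). LRRC32, which anchors latent TGFβ, rose by 3.55 ± 0.26 and SMAD3 by 1.03 ± 0.10, while the latent TGFβ binding protein gene LTBP4 fell, at -1.62 ± 0.21.

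BMP targets rose in 7 of 21 and fell in 3 (8 and 3 adjusted over the list alone), with a median of 0.45, 0.44 in RH6 and 0.26 in RH5 (camera adjusted p = 9.44e-04, and adjusted p = 0.1614 with an estimated correlation). The ligand gene BMP4 rose by 2.30 ± 0.19. Genes of LIF and STAT3 response rose in 6 of 18 and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 5.86e-04, and adjusted p = 0.1794 with an estimated correlation), among them IL6ST, a subunit of the LIF receptor, at 2.99 ± 0.14. Of 23 genes of MEK and ERK response, 9 rose and 5 fell (10 and 5 adjusted over the list alone), with a median of 0.37, 0.3 in RH6 and 0.56 in RH5 (camera adjusted p = 0.0227, and adjusted p = 0.1923 with an estimated correlation). The list was not called without primed RH5 (adjusted p = 0.9963) or with the naive libraries summed (0.0596). IER3 rose by 2.34 ± 0.14 and the ephrin receptor gene EPHA2 by 1.86 ± 0.12, while DUSP6, a phosphatase of ERK chosen after its value was seen, had -1.15. Of 26 genes of retinoic acid and NR5A2, 6 rose and 5 fell (8 and 5 adjusted over the list alone), with a median of 0.64, 0.16 in RH6 and 0.69 in RH5 (camera adjusted p = 0.0391, and adjusted p = 0.1799 with an estimated correlation). That call was lost without naive RH5 replicate 1 (adjusted p = 0.0522), naive RH5 replicate 2 (0.0617) or primed RH5 (0.3658). The transglutaminase gene TGM2 rose by 2.59 ± 0.23 and the corepressor gene NRIP1 by 1.51 ± 0.13.

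Markers of other cell types also moved. Of 21 tested genes of fibroblasts, the cell type of the feeders, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.87, 1.79 in RH6 and 0.79 in RH5 (camera adjusted p = 2.04e-10, and adjusted p = 0.1551 with an estimated correlation). The collagen gene COL3A1 rose by 4.33 ± 0.24, the collagen gene COL5A1 by 2.90 ± 0.18, the growth factor receptor gene PDGFRB by 2.38 ± 0.16 and the matrix metalloproteinase gene MMP2 by 3.16 ± 0.16. COL1A1, chosen after its value was seen, had 1.62 in RH6 and -0.36 in RH5. Of the 25 fibroblast genes found, 19 were at 1 CPM or more in both primed libraries and 4 were also in another list. Epithelial-mesenchymal genes rose in 14 of 22 and fell in 0 (15 and 0 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 1.01e-09, and adjusted p = 0.1022 with an estimated correlation). They included VIM at 1.53 ± 0.11, MMP2 and the integrin gene ITGA5 at 1.13 ± 0.12.

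Trophectoderm markers rose in 11 of 19 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 4.64e-08, and adjusted p = 0.1022 with an estimated correlation). HAND1 and TFAP2C were among them, the keratin gene KRT18 rose by 1.76 ± 0.21, and the homeobox gene CDX2 was 53.2-fold higher by summed counts, with a counting interval of 18 to 260. The keratin gene KRT7, chosen after its value was seen, fell, at -1.11 ± 0.22. ELF5, VGLL1, CGB and XAGE2 of this list had 8, 9, 1 and 0 counts over all 6 libraries and were not tested. Of the 23 trophectoderm genes found, 4 were also in another list, HAND1, TFAP2C and CDX2 among them. Mesendoderm and endoderm markers rose in 4 of 23 and fell in 3, also when adjusted over the list alone, with a median of 0.15, 1.75 in RH6 and -0.85 in RH5, or -0.81 with genes of 0 counts at their bound (camera adjusted p = 0.0107, and adjusted p = 0.5364 with an estimated correlation). HAND1, MIXL1 and T rose, and HHEX, a factor of early endoderm, fell, at -5.03 ± 0.40. The list was not called by fry (adjusted p = 0.1396), and without primed RH6 its direction turned (adjusted p = 0.9019). Neural and ectoderm markers fell in 8 of 17 and rose in 2 (9 and 3 adjusted over the list alone), with a median of -2.23, -3.28 in RH6 and -0.38 in RH5 (camera adjusted p = 4.46e-04, and adjusted p = 0.4903 with an estimated correlation). The eye and forebrain factor genes SIX3 and PAX6 had log2 fold changes of -6.37 ± 0.41 and -3.95 ± 0.34. RAX, another eye-field factor gene, was 110-fold lower by summed counts, with a counting interval of 37 to 538. Without primed RH6, which leaves the RH5 effect alone, camera did not call this list. The sign of its test turned there, though more of these genes fell than rose in RH5. With all libraries, fry did not call the list (adjusted p = 0.0842). Of 9 germ cell markers 2 rose and 2 fell, also when adjusted over the list alone, with a median of 0.51, 0.1 in RH6 and 0.11 in RH5, and a mean of -0.41 (camera adjusted p = 0.6901). The list was called by fry (adjusted p = 0.0080). PRDM1 rose by 1.49 ± 0.13 and KIT fell, at -1.81 ± 0.16.

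Cleavage-stage genes, which mark embryos around genome activation, rose in 7 of 8 tested and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.4015 with an estimated correlation). Their fitted median log2 fold change of 5.97 was 2.5 with the 6 genes that had 0 primed counts at their bound. The counts of TRIM43 (129 in naive libraries), TRIM49 (106) and KDM4E (98) all came from the naive RH5 libraries and were 0 in naive RH6 and in primed cells. TRIM43 was at least 22.3-fold, TRIM49 at least 18.3-fold, KDM4E at least 16.9-fold and ZSCAN4, with 31 counts, at least 5.36-fold higher in naive than in primed cells. These 4 calls were lost with DESeq2 (adjusted p = 0.7159, 0.7167, 0.7169 and 0.0849) and without the line term (0.1778 to 0.1833), and without primed RH5 (1.0000 for the 3 and 0.5546 for ZSCAN4). ZSCAN4 was also not called with limma-voom (0.0784), without naive RH6 replicate 1 (0.0524) or without naive RH6 replicate 2 (0.0541). The list was not called by fry (adjusted p = 0.1637), without naive RH5 replicate 1 (0.4563), naive RH5 replicate 2 (0.3926) or primed RH5 (0.7650), or with the naive libraries summed (0.2738). Several of these genes belong to families of near-identical copies whose reads the counting may have split, so their counts are uncertain.

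Genes of sterol synthesis rose nearly throughout, in 19 of 21 with 0 lower (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 1.65e-14, and adjusted p = 0.1614 with an estimated correlation). INSIG1, a regulator of sterol sensing, rose by 1.58 ± 0.11 and the synthesis enzyme gene HMGCS1 by 1.20 ± 0.11. Targets of p53 rose in 9 of 22 and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.43, 0.59 in RH6 and 0.24 in RH5 (camera adjusted p = 0.0020, and adjusted p = 0.1614 with an estimated correlation), among them BTG2 at 1.86 ± 0.29, ZMAT3 at 1.09 ± 0.11 and C12orf5, which encodes TIGAR, at 1.11 ± 0.14. Heat shock and handling stress genes rose in 4 of 15 and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.3652 with an estimated correlation). Their median was -0.04, -0.2 in RH6 and 0.68 in RH5, and their mean 0.31, with KLF6 at 1.85 ± 0.10 and the cochaperone gene BAG3 at 1.30 ± 0.13. This call was lost with fry (adjusted p = 0.0516) and without primed RH5 (0.7650).

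The remaining lists were not called. Of 22 imprinted genes 3 rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.2486), with H19 at 4.43 ± 0.16 and SNRPN at -1.15 ± 0.11. Of 17 genes of the DNA methylation machinery 3 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.5543), and fry called the list (adjusted p = 0.0383). Of 22 glycolysis genes 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.1930), among them the enolase gene ENO1 at 0.79 ± 0.12, whose call was lost with the naive libraries summed (0.0769). The glycolysis list was called without primed RH5 (adjusted p = 0.0012) and with no low-count filter (0.0312). Of 42 nuclear genes of oxidative phosphorylation 4 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.2486), and the list was called with no low-count filter (0.0299). Of 18 genes of amino acid stress 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.2486), among them ATF3 at 1.51 ± 0.11. That list was called without primed RH5 (adjusted p = 0.0124). Of 27 genes of cell proliferation 5 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.4851), with the kinetochore motor gene CENPE at 1.04 ± 0.17. In all, 18 of the 26 lists with tested genes were called by camera at the preset correlation, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 16 by fry.

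**Figure D3:**
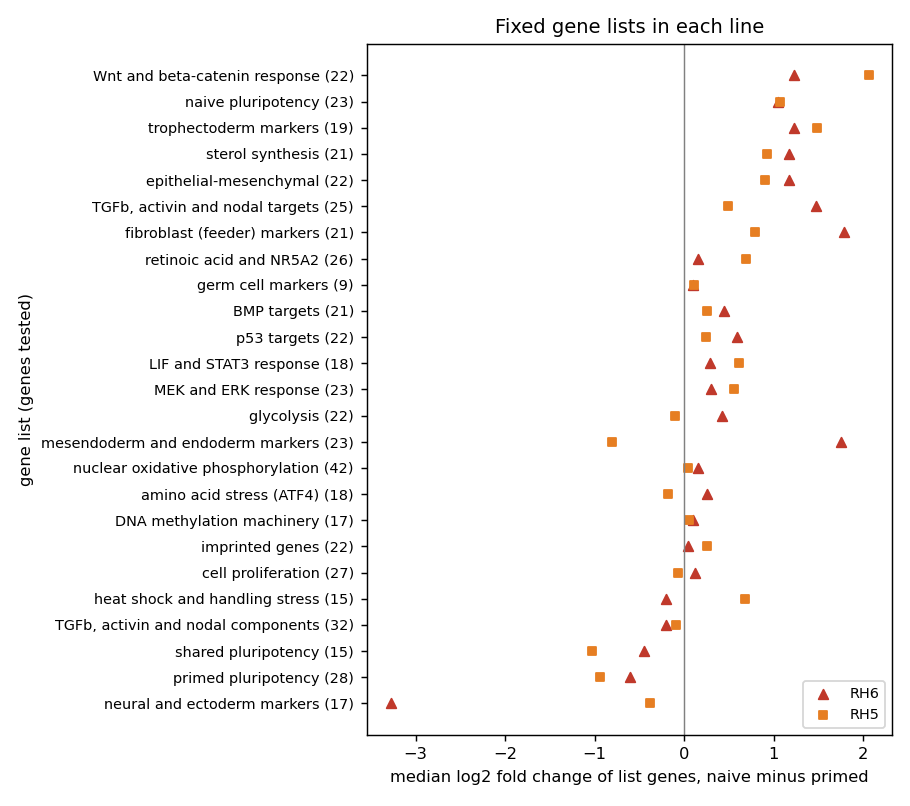
Median log2 fold change, naive minus primed, of the tested genes of 25 of the 26 tested lists on the horizontal axis, in RH6 (triangles) and RH5 (squares), with the number of tested genes after each name. Genes with 0 counts in a group were set to their bound, and those with 3 or fewer counts in both groups were left out. The cleavage-stage list, at 0.54 over 2 genes in RH6 and 3.05 over 8 in RH5, was not drawn. The Wnt list stood at 1.23 in RH6 and 2.06 in RH5, and the mesendoderm list at 1.75 in RH6 and -0.81 in RH5.

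Within each line, the same comparison asked whether the state effect held in that line alone. Sterol synthesis genes rose in 20 of 21 in RH6 and 17 of 21 in RH5, and Wnt response genes in 16 and 18 of 22. Targets of TGFβ, activin and nodal rose in 20 of 25 in RH6 and 15 in RH5, and fibroblast genes in 16 of 21 in RH6 and 10 in RH5. Primed pluripotency genes fell in 17 of 28 in RH6 and 19 in RH5. HAND1 had 6.35 in RH6 and 7.19 in RH5 and MACC1 -4.87 and -5.06 on the log2 scale, without a called difference (adjusted p = 0.4271 and 0.6728), while HPGD had 8.02 and 6.33 with a called difference (adjusted p = 0.0095). In RH6, 6531 genes were called, 3186 higher and 3345 lower in naive cells, and in RH5 6512, of which 3210 were higher and 3302 lower. DESeq2 called 4032 genes in RH6 and 3919 in RH5. A total of 3468 genes were called in the same direction in both lines, 1607 higher and 1861 lower, where independent lists would share 527 and 570, and 307 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at r = 0.58 (Spearman's rho 0.51), and 68% of all genes had the same sign. Each line had 1 primed library, so the tests within a line rest on the spread of the naive duplicates.

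The test of the difference asked which genes responded differently in the lines. Under the naming rule, which takes genes with a mean log2 CPM of 3 or more, the imprinted gene PEG3 (ENSG00000198300) had the highest difference, the RH6 effect minus the RH5 effect being 8.77 ± 0.30 on the log2 scale (adjusted p = 6.92e-07). It stood at 17.8 CPM in naive RH6 and 18.9 CPM in naive RH5, against 0.40 CPM in primed RH6 and 190.9 CPM in primed RH5. The cystatin gene CST1 (ENSG00000170373) differed by 6.14 ± 0.31, the lipid flippase gene ATP8A2 (ENSG00000132932) by 4.88 ± 0.25, LEFTY2 by 4.27 ± 0.18 and the receptor gene ERBB4 (ENSG00000178568) by 4.15 ± 0.28. At the other end stood genes that fell in RH6 and rose in RH5, namely the neuronal gene MAP2 (ENSG00000078018) at -5.69 ± 0.23, the transcription factor genes LMX1B (ENSG00000136944) at -5.54 ± 0.29, EGR3 (ENSG00000179388) at -5.37 ± 0.20 and EGR2 (ENSG00000122877) at -5.03 ± 0.30, and the retinoic acid binding protein gene CRABP1 (ENSG00000166426) at -5.18 ± 0.21. NR5A2 differed by 1.91 ± 0.21 (adjusted p = 3.41e-04) and NANOG by 1.27 ± 0.19 (adjusted p = 0.0021). In all, 2361 genes were called, 1154 with a positive and 1207 with a negative value of the RH6 effect minus the RH5 effect. DESeq2 called 1303. A total of 2756 genes were called in RH6 and not RH5, and 2737 in RH5 and not RH6. Of these genes called in 1 line only, 1447 had a called difference and most had none. Mesendoderm and endoderm genes rose in 15 of 23 and fell in 3 in RH6 but rose in 7 and fell in 10 in RH5, and 15 of them had a called difference. The endoderm genes SOX17 and FOXA2, chosen after their values were seen, stood at 0.81 and 0.94 CPM in primed RH6 and at 7.54 and 7.91 CPM in primed RH5. Neural genes fell in 12 of 17 and rose in 3 in RH6 and fell in 7 and rose in 5 in RH5, and 10 had a called difference. PAX6 stood at 36.8 CPM in primed RH6 and 12.1 CPM in primed RH5.

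**Figure D4:**
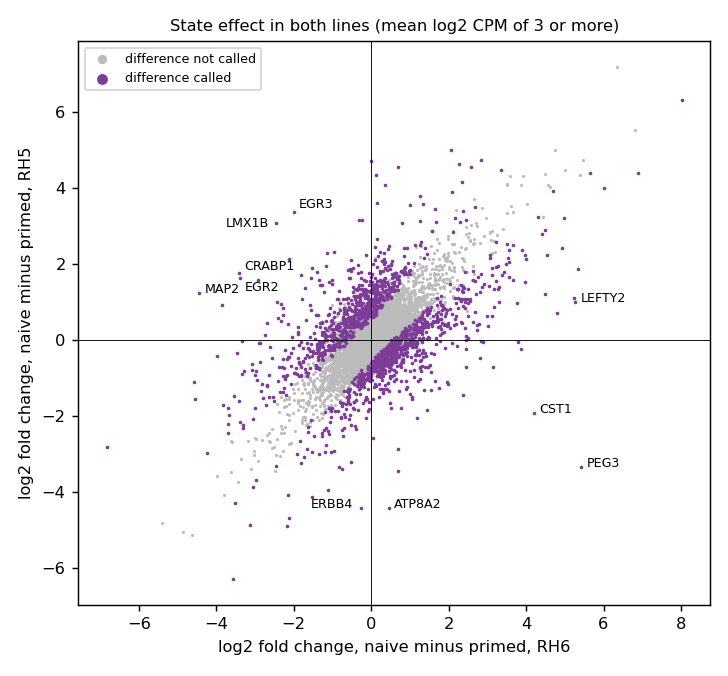
Log2 fold change, naive minus primed, in RH6 on the horizontal and in RH5 on the vertical axis, for the 10302 genes with a mean log2 CPM of 3 or more. Purple points are the 1609 genes with a called difference between the lines, and the 5 highest and 5 lowest under the naming rule are labelled, PEG3 lying at 5.43 in RH6 and -3.34 in RH5.

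The last comparison set naive RH6 against naive RH5, with 2 libraries each. ATP8A2 stood at 48.5 CPM in naive RH6 and 1.09 CPM in naive RH5, a log2 fold change of 5.46 ± 0.17 (adjusted p = 1.21e-07). The genes LIN7A (ENSG00000111052), CBLN1 (ENSG00000102924), GALNT3 (ENSG00000115339) and SHISA2 (ENSG00000180730) were higher in naive RH6 by 3.86 ± 0.14, 3.68 ± 0.14, 3.27 ± 0.18 and 3.24 ± 0.19. Higher in naive RH5 were CRABP1, at 111.5 CPM against 4.72 CPM and a log2 fold change of -4.56 ± 0.14, LMX1B at -4.35 ± 0.17, EGR3 at -4.23 ± 0.12, SLFN13 (ENSG00000154760) at -4.11 ± 0.18 and EGR2 at -4.09 ± 0.19. The adjusted p-values of these 10 genes were 1.07e-07 to 2.31e-06. TRIM43 was at least 43.5-fold, TRIM49 at least 35.7-fold and KDM4E at least 33-fold higher in naive RH5. A total of 4932 genes were called, 2310 higher in RH6 and 2622 in RH5, of which 696 and 1409 changed at least 2-fold. DESeq2 called 2832. The lines differed in passage number, 10 for naive RH6 and 17 for naive RH5, so line and passage could not be separated.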

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

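Of the tests of explanations given here, the one on olfactory receptor genes was set out before its result was seen, and all others were chosen after. The comparison of gene lists between the lines was also added after the data had been seen. The genes and lists below had a naive against primed effect that differed between RH6 and RH5 by edgeR's quasi-likelihood test or by camera. Differences are the RH6 effect minus the RH5 effect on the log2 scale. Each rests on 2 naive libraries and 1 primed library per line.

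Among genes named for their role, NR5A2 differed by 1.91, NANOG by 1.27, NODAL by 1.76, LEFTY1 by 1.65, LEFTY2 by 4.27, SMAD7 by -0.79 and ZIC2 by 1.18. Of the strongest genes of the main comparison, T differed by 2.47, HPGD by 1.68, GPR176 by 2.74, RMST by 1.76, SFRP1 by 0.76 and SOX21 by -4.01. Of the other genes named for the difference, all with a mean log2 CPM of 3 or more, PEG3 stood at 8.77, CST1 at 6.14, ATP8A2 at 4.88 and ERBB4 at 4.15, and on the negative side MAP2 at -5.69, LMX1B at -5.54, EGR3 at -5.37, CRABP1 at -5.18 and EGR2 at -5.03. Of the genes named between the naive lines, GALNT3 differed by 4.15, CBLN1 by 3.07, LIN7A by 2.61, SHISA2 by 2.55 and SLFN13 by -2.81. Members of lists that differed were STC2 (0.94), KRT18 (0.85), PMEPA1 (0.81), SLC3A2 (0.79), JARID2 (0.73), COL5A1 (0.64), BNIP3 (0.61) and TAGLN (0.56). On the negative side they were PIM1 (-0.84), LTBP4 (-0.91), ZDBF2 (-1.17), BTG2 (-1.25), PAX6 (-1.58) and IGF2 (-2.24). Adjusted p-values of these genes ran from 6.92e-07 for PEG3 to 0.0472 for BNIP3.

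Of the lists, mesendoderm and endoderm markers had a median difference of 2.38 (camera adjusted p = 3.38e-20, and adjusted p = 0.2301 with an estimated correlation) and neural and ectoderm markers of -1.73 (4.21e-13, and 0.2789 with an estimated correlation). Targets of TGFβ, activin and nodal had 0.56 (4.18e-07, and 0.2789), primed pluripotency genes 0.55 (3.91e-07, and 0.2789), glycolysis genes 0.49 (1.05e-04, and 0.4130) and heat shock genes -0.55 (1.05e-04, and 0.3931). Amino acid stress genes had 0.58 (8.82e-04, and 0.3931), fibroblast genes 0.06 (0.0026, and 0.4395), shared pluripotency genes 0.54 (0.0066, and 0.3931), MEK and ERK response genes -0.28 (0.0142, and 0.3931), retinoic acid and NR5A2 genes -0.15 (0.0274, and 0.3931) and sterol synthesis genes 0.27 (0.0464, and 0.5794). Naive pluripotency genes had 0.21 (0.0139, and 0.3931), or 0.34 over the 22 genes counted in every group. In this series of pairs the second value is the adjusted p with an estimated correlation, under which 0 of the 26 lists passed (4 at an unadjusted p under 0.05).

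Fibroblast and Wnt response genes were higher in naive cells by camera at the preset correlation (adjusted p = 0.1551 and 0.1022 with an estimated correlation). RNA of feeder fibroblasts would bring the collagen genes up together, and in RH5 COL3A1 and COL1A2 rose by 4.04 and 1.37 while COL1A1 had -0.36 ± 0.17. In RH6, COL3A1, COL1A1 and COL1A2 rose by 4.62, 1.62 and 0.94, while DCN, an abundant fibroblast gene, stood at 0.072 CPM. How mouse reads were counted per human gene is not known, so in both lines feeder RNA and expression by the naive cells cannot be told apart. A share of differentiated cells stays open too, since POU5F1 had 0.22 and SOX2 -1.33, 10 of 15 shared pluripotency genes fell, and the high level of POU5F1 can hide a small share, and an effect of the naive medium, which changed with the state, is open as well.

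Cleavage-stage genes were counted in the naive RH5 libraries, where 14 of the 17 list genes found were highest in both libraries by CPM, some of them at 1 to 3 counts, with TPRX1 at 1 count in naive RH5 replicate 2 and in primed RH6. Genomic DNA would raise olfactory receptor genes, whose summed CPM over 514 genes was 1.01 times as high in naive RH5 as in naive RH6. That value covers the comparison of the naive lines only. Primed RH5 was lower, at 8.85 CPM against 14.73 and 13.62 CPM in the naive RH5 libraries, while primed RH6 stood at 12.83 CPM. Reads shared between paralogs would not raise CCNA1, which had a log2 fold change of -3.46 in naive RH6 against naive RH5. Members of multicopy families were picked by symbol, without a check of their sequences, and 9 of 9 were highest in naive RH5. Where such a gene has near-identical copies, reads split between copies and expression of the named copy cannot be told apart from counts per gene. A cleavage-stage programme in naive RH5, in rare cells or in many, stays open, as does the passage number.

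The state effect differed between the lines in 2361 genes. The gap between the 2 primed libraries, each the only one of its line, was larger than the gap between the naive lines in 31.3% of them. The share was 46.2% in genes without a called difference. For most called genes the primed gap was thus not the larger of the 2. It still enters every difference, and the error of a lone primed library was not measured. A contribution of the primed libraries is therefore not excluded. Among the 5 highest named genes, PEG3, CST1, LEFTY2 and ERBB4 had the larger gap between the primed libraries, PEG3 with 0.403 CPM in primed RH6 and 190.9 CPM in primed RH5, so for these genes that explanation stays open. For mesendoderm and neural genes with a called difference the share was 60% of 25 genes, too near an even split to decide, so a difference between the primed cultures stays open there. Passage number, 10 in naive RH6 and 17 in naive RH5, changed with the line, so the effects of passage and of the lines themselves cannot be told apart.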

How the results depend on the processing

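For naive against primed, 2351 higher and 2649 lower genes became 1331 to 3430 and 1602 to 3280 when each library was left out in turn, lowest without a naive and highest without a primed library. With the naive libraries of each line summed, 495 and 630 were called, on fewer libraries. Without the line term 1617 and 1967 were called. Of the 5000 genes, 4689 were called in the same direction with DESeq2, 4866 with limma-voom, 4955 with RLE factors, 4606 with upper-quartile factors, 3580 without the line term and 1123 with summed libraries, and 0 in the opposite direction in any of these. Upper-quartile factors moved the median log2 fold change of all genes from -0.007 to -0.089 and the share of higher calls from 47% to 37.9%. DESeq2 called 1888 lower genes in RH6 (main 3345), 2094 higher and 1825 lower in RH5, 657 and 646 for the difference between the lines, and 1327 and 1505 for naive RH6 against naive RH5. The cause was not tested.

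Of the 117 genes named for naive against primed, 15 lost the call without the line term, and 25 of the 112 with a value lost it with summed libraries, while RLE factors, upper-quartile factors and leaving out histone genes changed none. The 10 genes named for the difference and the 10 for the naive lines kept direction and call in every alternative run. Leaving out a line's lone primed library gave no value for that line's own effect or for the difference.

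Camera called 18 lists at the preset correlation and 0 with an estimated correlation. Mesendoderm and endoderm markers had adjusted p-values of 3.25e-13 without primed RH5 to 0.9019 without primed RH6, and neural and ectoderm markers of 6.99e-14 to 0.9905. In both, the sign of camera's test turned without primed RH6, because the fit then holds the RH5 effect alone. Neither list was called there, and the median of the neural list in RH5 was still below 0, at -0.38.

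With the replicate number as a block, naive RH6 against naive RH5 gave 3740 higher and 3630 lower genes on the 4 naive libraries, against 5001 in all without the block. Across the 19389 genes tested, the differences between replicates 1 and 2 correlated at 0.14 between RH6 and RH5. On the third principal component, replicate 1 lay at -3.2 in naive RH6 and -5 in naive RH5, and replicate 2 at 4.6 and 6.8. These are 2 pairs of libraries, too few to show whether the numbers pair them, so a shared effect of the replicate number is not excluded. MALAT1 took 0.712% and 0.998% of counts in naive RH6 replicates 1 and 2 and 0.989% and 1.259% in naive RH5. It took 1.744% in primed RH6 and 1.226% in primed RH5. MIR663A took 0.767% in primed RH6 and 1.211% to 1.576% in the other libraries. Primed RH6, the only primed library of its line, thus differed in these shares, and whether this moved its comparisons was not tested. The labels name no shared batch. Genes with few counts, such as KLF17 with 33 naive counts, are limited by depth.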

Other observations

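The tests in this part were chosen after the data had been seen, as were the genes named. Fisher's exact test treats genes as independent, though all came from the same 6 libraries and genes of a family can move together. Its p-values here do not measure the spread between libraries, and may be too small. HOX genes, the homeobox genes that pattern the body axis, rose in naive cells in 18 of 21 tested genes and fell in 0. This was 85.7% of the family against 13.3% of other protein-coding genes (Fisher's exact test, adjusted p = 2.94e-11 over 176 tests of families and directions). Primed means of the 21 genes were 0 to 0.789 CPM, so the low-count filter kept them through their naive libraries. HOX genes with few counts in both states were not tested. The share called, its p-value and the 0 that fell were thus partly set by the filter. The same holds for the sign of the 21 fold changes below. HOXB1 stood at a mean of 7.35 CPM in naive RH6 and 55.8 CPM in naive RH5 against 0.509 CPM in primed cells, and HOXB2 at 8.95 and 30.3 CPM against 0.556 CPM. The log2 fold changes of HOXB2, HOXC8 and HOXB3 were 4.94 ± 0.42, 4.93 ± 0.48 and 4.52 ± 0.25. The median log2 fold change was 4.93 as fitted and 4.09 with 4 genes of 0 primed counts at their bound. With bounds it was 2.37 in RH6, where 7 of 19 genes were at their bound, and 4.05 in RH5, where 4 of 21 were. Of 23 mesendoderm and endoderm markers 4 rose, T (5.34), MIXL1 (5.02) and HAND1 (6.67) among them, and 3 fell, with HHEX at -5.03, and the direction of that list turned without primed RH6 (adjusted p = 0.9019). Of 21 fibroblast genes 10 rose and 1 fell. In RH6, 13 of the HOX genes were called higher and in RH5 20. Over both lines together, all 21 had a positive log2 fold change with TMM, RLE and upper-quartile factors, DESeq2 and limma-voom, while in RH6 alone HOXB9 stood at -0.31, HOXC10 at -0.30 and HOXA2 at 0.01. HOX genes overlap and neighbour antisense genes, and the strand setting of the counting is not known.

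Synaptotagmin genes, whose products act in the release of vesicles, fell in naive cells in 11 of 16, or 68.8% against 16% of other protein-coding genes (Fisher's exact test, adjusted p = 3.06e-04). This p-value too treats the genes as independent. Their median log2 fold change was -1.59, and -1.67 to -1.55 under the other scalings and tools. In RH6 13 of them fell and in RH5 12, with SYT13 over both lines at -1.93 ± 0.24 and SYT6 at -1.47 ± 0.16. Neural and ectoderm markers fell with them in 8 of 17 over both lines, with SIX3 at -6.37 and PAX6 at -3.95. The median of that list was -3.28 in RH6 and -0.38 in RH5, and camera did not call it without primed RH6.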
